A study of Mus musculus with 6 samples.

How the data were processed

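Total RNA from the kidney cortex of male C57BL/6 mice was sequenced after a stranded library preparation that selects polyadenylated RNA, per the labels. The 6 libraries were grouped by their labels into IRI kidney and IRI kidney with renal congestion, with 3 replicates each. The deposited table holds whole-number counts of reads per gene, not normalized, with 1 column per sample, which the values themselves show. STAR 2.7.10a, featureCounts, Subread and the genome build GRCm38 are named per the submitters' processing notes, without the role of each. Aligner parameters, the gene annotation and the strand setting of the counting are not given in the sources used here, so overlapping and antisense genes may share reads. Multimapping rules are also not given, and genes with near-identical copies (Klk1, Chil3, Rn18s-rs5 and haemoglobin genes) are reported as uncertain.

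The table held 26971 features. Of these, 258 had an identifier in place of a symbol and held 0.0272% of the counts, and 20 symbols stood on 2 features each, which were kept apart. Total counts per library ranged from 10865860 to 14350425. Mitochondrially encoded genes were not analysed here. Replicates of a group differed by more than sampling noise, with a chi-square per degree of freedom of 17.2 to 175 between pairs, so none was treated as a second count of the same library. This test cannot tell whether any of them came from the same animal.

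Counts were tested with edgeR 4.0.16 in R 4.3.3, using TMM factors, the filterByExpr filter (minimum count 10, minimum total 15), which left 14274 genes, and a robust quasi-likelihood F test with group as its term. P-values were adjusted by the Benjamini-Hochberg method, and genes were called at an adjusted p under 0.05. Normalized values are TMM-scaled CPM, and log2 CPM used a prior count of 2. Gene lists were tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, and again with an estimated correlation and with fry. The 33 lists, the tests, the main alternatives and the rule for naming genes were fixed before the data were examined. A list was tested where at least 3 members passed the filter. Shares of counts were compared by exact two-sided permutation tests over 6 measures.

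The rule named Ccn1 and the measured CCN family, the 10 genes with the largest change in each direction among called genes with a mean of at least 5 CPM and groups that do not overlap, and up to 3 called members of each list, or the 2 with the smallest p where none was called. No gene was called, so the part of the rule on size of change named 0 genes. Genes called by DESeq2 with the replicate block, and the 10 genes with the smallest p in each direction, were named after their values were seen.

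The labels number the replicates 1 to 3 in both groups without saying what a number shares. Sample titles name the groups CLK_IRI and Cong_IRI, and the count columns CLK_IRI and IVCC_IRI, without expanding CLK or IVCC. Whether a shared number marks the same animal is not known, and the test without the block ignores any such pairing. Deviations from the group means correlated across genes at 0.724, 0.342 and 0.429 between samples numbered 1, 2 and 3, each above 0.1. The numbers were taken to pair the samples, although the labels do not say so. Replicates 2 and 3 also correlated when crossed. The value was 0.401 for IRI replicate 2 with congested replicate 3 and 0.249 for IRI replicate 3 with congested replicate 2. Deviations within a group cancel out, so with replicate 1 apart from the others this holds under either matching. The data thus match replicate 1 alone, and the pairing of replicates 2 and 3 rests on their numbers. The common biological coefficient of variation was 0.337 without and 0.211 with the replicate number as a block.

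Alternatives were other scaling factors, other filters on low counts, DESeq2 1.42.0, limma-voom, a fit without robust dispersion, the replicate block, counts thinned to equal depth and each library left out in turn. Added after the data were seen were a per-library trend in transcript length and GC content removed as an offset (mgcv 1.9.3, basis 6), DESeq2 and limma-voom with the block, each replicate number left out of both groups, the count of genes at an unadjusted p under 0.05 and the share of Rn18s-rs5. Transcript lengths, GC content and coordinates came from the GENCODE annotation of GRCm38, which matched 97.5% of tested genes. Length and GC content were those of the longest annotated transcript of each gene. The median difference of all genes was 0.007 with TMM, -0.002 with RLE, 0.005 with upper-quartile factors and 0.11 with total counts.

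The fit was tested on simulated data with the real genes, means and library sizes and 100 genes each changed 2-fold and 4-fold in congested against IRI libraries. Without the block 70 of 14012 genes were called, 4 of them unchanged, and with it 164 of 14064, 15 of them unchanged. A planted list was recovered at a camera adjusted p of 1.06e-15, and 1 of 30 unchanged lists was called without the block and 0 with it. Simulated genes varied independently of each other, and the planted change was larger than the medians of the lists called without the block. These counts therefore cannot show how often camera calls unchanged lists when genes vary together. Figures were drawn with Matplotlib 3.10.9 in Python 3.11.15.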

Results

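Polyadenylated RNA from the kidney cortex of male C57BL/6 mice was profiled by RNA sequencing 1 day after surgery. IRI is the usual abbreviation for ischaemia-reperfusion injury, in which blood flow to the kidney is stopped and then restored. The 6 libraries fell into 2 groups of 3, IRI kidney and IRI kidney with added renal congestion, each numbered 1 to 3 in the labels. Total counts were 14350425, 11976816 and 10865860 in IRI replicates 1, 2 and 3, and 11376642, 12856600 and 11980864 in congested replicates 1, 2 and 3. The labels do not say that the samples came from separate animals, so the p-values measure only the spread between these samples. The comparison asked how congestion alters the transcriptome of the injured kidney, with Ccn1, the gene in the title of the series, as its focus.

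The first principal component of the 1000 most variable genes held 68.2% of their variance and set replicate 1 of both groups, at -39.6 and -41.8, apart from the other 4 libraries, at 10.2 to 32.9. In edgeR, 1144 of 14274 genes differed between the replicate numbers at adjusted p under 0.05, among them Spp1, Lcn2 and Havcr1, which are tubular injury genes.

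**Figure D1:**
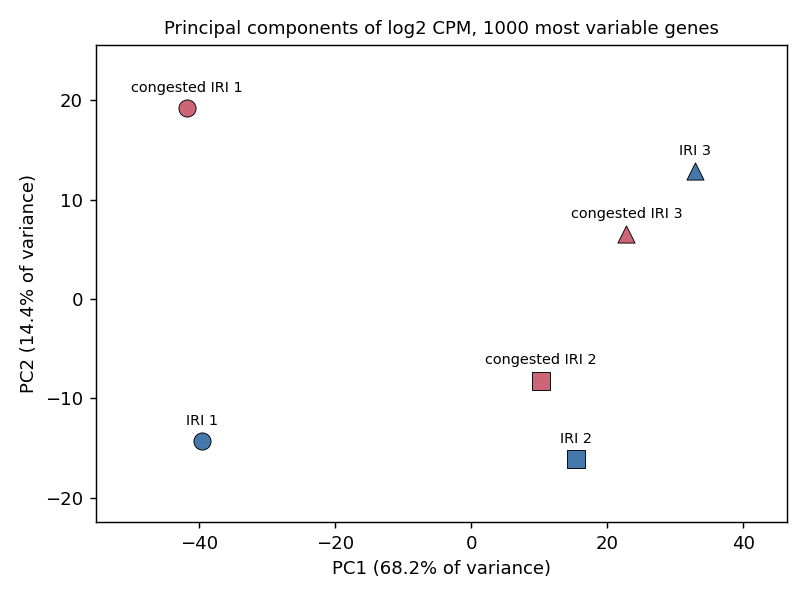
Principal components of log2 CPM for the 6 libraries, with PC1 (68.2% of variance) on the horizontal axis, PC2 (14.4%) on the vertical axis, 1 point per library, colour for the group (blue IRI, red congested IRI) and marker shape for the replicate number. Replicate 1 of both groups lies at the left, apart from replicates 2 and 3.

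Ccn1, a secreted matricellular protein and a target of the YAP/TEAD pathway, was not separated between the groups. Its normalized level was 126.7 ± 137.1 CPM (SD, n = 3) in IRI and 142.8 ± 64.7 CPM (SD, n = 3) in congested IRI kidney. The log2 fold change was 0.17 with a standard error of 0.74, and edgeR's quasi-likelihood test gave an adjusted p of 0.969. IRI replicates 1, 2 and 3 held 284.5, 58.7 and 37.0 CPM, and the congested replicates 214.3, 125.8 and 88.3 CPM. Within libraries of the same number the congested kidney was lower by log2 -0.41 in replicate 1 and higher by 1.10 and 1.25 in replicates 2 and 3. With the replicate number as a block the log2 fold change was 0.65 with a standard error of 0.33, and edgeR's adjusted p was 0.577. Without IRI replicate 1 the log2 fold change was 1.58, whereas it was -0.17 without IRI replicate 2, -0.26 without IRI replicate 3 and -0.26 without congested replicate 1. Ccn1 lies on chromosome 3 from 145646976 to 145649981 on the minus strand of GRCm38 and is annotated as protein-coding. Because the series is named for it, the gene may have been chosen from these libraries, so its test is not independent evidence of a direction.

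Of the other members of the CCN family, Ccn2 had a log2 fold change of 0.20 (standard error 0.87, edgeR adjusted p = 0.970) and Ccn4 one of 0.42 (standard error 0.33, edgeR adjusted p = 0.933). All 3 tested members of the family lay above 0, with a camera adjusted p of 0.249 and an adjusted p of 0.845 with an estimated correlation. The family was called by DESeq2 with the block (median 0.55, camera adjusted p = 0.0311, against an adjusted p = 0.559 with an estimated correlation in edgeR) and by edgeR with the block and a length and GC trend removed (0.61, 0.0398, adjusted p = 0.387 with an estimated correlation). It was also called without IRI replicate 1 (1.58, 0.00149), whereas its median was -0.17 without IRI replicate 2, -0.24 without IRI replicate 3 and -0.26 without congested replicate 1. The log2 fold change of Ccn2 was 1.78, -0.19 and -0.24 without IRI replicates 1, 2 and 3 in turn. It was -0.62, 0.58 and 0.38 without congested replicates 1, 2 and 3. That of Ccn4 was 0.23 without congested replicate 2. Ccn3 and Ccn5 did not pass the filter on low counts.

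**Figure D2:**
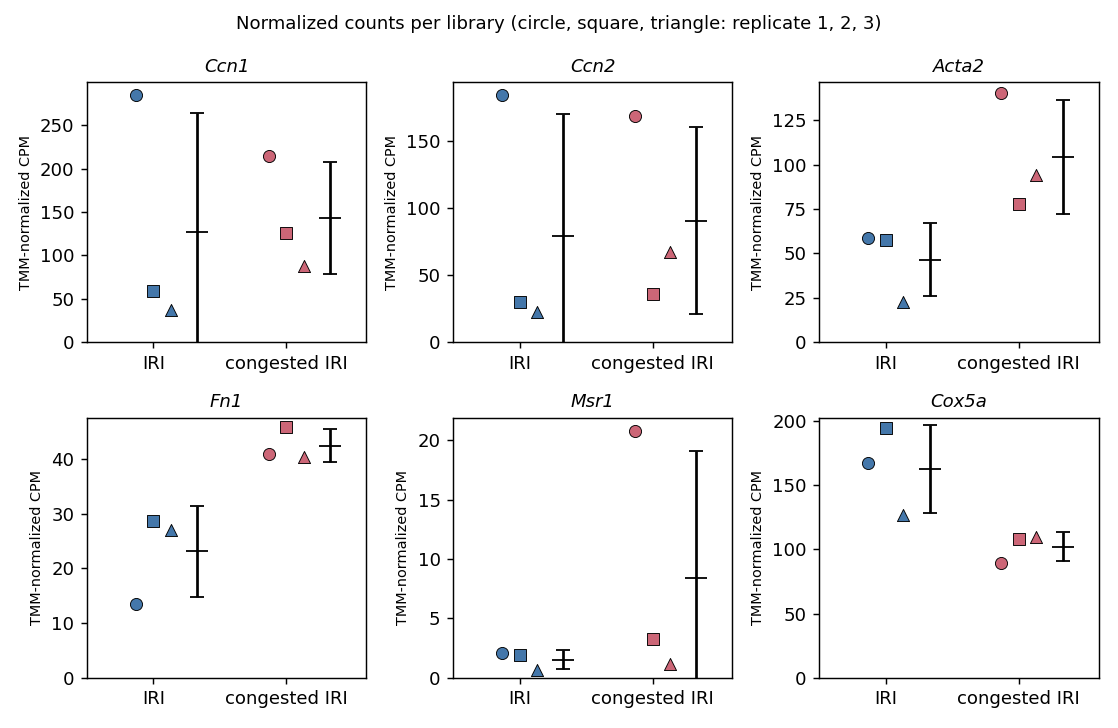
Normalized counts of 6 genes in each library, in CPM on a linear axis from 0, for IRI (blue) and congested IRI (red), with circles, squares and triangles for replicates 1, 2 and 3 and a black bar for the mean with its SD (n = 3), clipped at 0 for the IRI groups of Ccn1 and Ccn2 and the congested group of Msr1. Acta2, Fn1 and Cox5a do not overlap between the groups, whereas Ccn1 and Ccn2 do.

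No single gene passed the threshold in the comparison of congested with non-congested IRI kidney. Among the genes whose groups did not overlap, Fn1 (fibronectin) was 1.84-fold and Acta2 (smooth muscle actin) 2.25-fold higher in the congested kidney, both at an edgeR adjusted p of 0.933. The receptor tyrosine kinase gene Axl had a log2 fold change of 0.74 with a standard error of 0.20, at 19.3 ± 2.93 against 32.2 ± 0.394 CPM (SD, n = 3). In the other direction Cox5a, a subunit of cytochrome c oxidase, lay at 162.8 ± 34.4 against 102.2 ± 11.4 CPM (SD, n = 3), a log2 fold change of -0.67 with a standard error of 0.23. edgeR called 0 genes higher and 0 lower, hence 0 with a fold of 2 or more; 285 genes had an unadjusted p under 0.05, 141 higher and 144 lower, and the smallest adjusted p was 0.933. DESeq2 and limma-voom also called 0 genes, with 341 and 276 at an unadjusted p under 0.05. The 3 congested libraries all lay on one side of the 3 IRI libraries in 6.49% of genes, where chance gives 10% for unpaired libraries. Within replicate numbers, 26.1% of genes differed in the same direction in all 3 pairs, where chance gives 25%. With the replicate number as a block edgeR again called 0 genes, with 1008 at an unadjusted p under 0.05. On simulated counts with this spread the test without the block recovered 6% of genes changed 2-fold and 60% of those changed 4-fold, and with the block 52% and 97%.

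DESeq2 with the replicate block called 10 genes, named here after their values were seen. Of these, 7 rose in the congested kidney: the chemokines Ccl9 and Ccl6, the macrophage and neutrophil genes Chil3 and S100a8, the acute-phase gene Hp, the actin-binding Flna, and Acta2. Ccl9 had a log2 fold change of 2.05 with a standard error of 0.39 (DESeq2 adjusted p = 8.24e-04), with differences of 2.40, 1.94 and 1.28 in replicates 1, 2 and 3. Flna had a log2 fold change of 0.97 with a standard error of 0.21 (DESeq2 adjusted p = 0.0128). It differed by 0.99, 0.93 and 1.00 in the 3 replicates. Its transcript has 8456 bases. In edgeR with the block its log2 fold change was 0.98, and 0.65 with a length and GC trend removed. The 3 that fell were Mgp, which encodes an inhibitor of calcification, Apoc3, and the ribosomal RNA gene Rn18s-rs5. Counts of Chil3 and Rn18s-rs5 are uncertain because near-identical copies exist. The libraries were selected for polyadenylated RNA, so counts of Rn18s-rs5 may not measure the level of ribosomal RNA. They lay at 3815, 5844 and 1813 CPM in IRI replicates 1, 2 and 3. The congested replicates held 1579, 1598 and 1388 CPM. None of the 10 passed edgeR with the same block, whose smallest adjusted p was 0.577. S100a8 differed by 1.56, 1.21 and 1.13 in replicates 1, 2 and 3, and Chil3 by 2.72, 2.12 and 0.105. In replicate 3 Chil3 lay at 0.353 CPM in IRI and 0.392 in congested kidney. A fit without the block and without 1 library leaves the other library of that number unmatched. Its values therefore also carry differences between replicates. In edgeR without the block, leaving out congested replicate 1 gave log2 fold changes of 0.20 for Ccl9, 0.59 for Ccl6, -1.81 for Chil3, -1.10 for S100a8, -0.50 for Apoc3 and -0.79 for Mgp, against 2.29, 2.56, 2.69, 1.52, -0.97 and -1.22 with all libraries. Leaving out IRI replicate 1 gave 3.90 for Ccl9, 6.401 for Chil3 and 3.88 for S100a8, IRI replicate 2 -0.89 for Rn18s-rs5 and -0.73 for Mgp, IRI replicate 3 -0.60 for Apoc3 and 1.01 for S100a8, congested replicate 2 1.47 for Hp and congested replicate 3 -2.15 for Apoc3.

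Extracellular matrix and myofibroblast genes rose in the congested kidney by camera, with 21 of 22 members above 0, a median log2 fold change of 0.34 and an adjusted p of 2.43e-04 (adjusted p = 0.845 with an estimated correlation). Its members with the smallest p were Fn1 and Acta2, with log2 fold changes of 0.88 (standard error 0.30) and 1.17 (standard error 0.40). YAP/TEAD targets also rose, 17 of 21 members lying above 0 with a median of 0.29 (camera adjusted p = 6.21e-04, adjusted p = 0.845 with an estimated correlation). Their members with the smallest p were Axl and Myof, with log2 fold changes of 0.74 and 0.61. Immediate early genes, the first transcription factors induced by stress, rose with 16 of 20 members above 0 and a median of 0.33 (camera adjusted p = 0.0229, adjusted p = 0.845 with an estimated correlation). In that list Fos had a log2 fold change of 1.08 (standard error 0.56) and Klf6 one of 0.88 (standard error 0.53). That of Fos was 1.90 without IRI replicate 1 and 0.68 without IRI replicate 3. That of Klf6 was 1.42 without IRI replicate 1 and 0.27 without congested replicate 1. Neither the matrix list nor the immediate early list was called without IRI replicate 3, at adjusted p = 0.375 and 0.841, and the immediate early list was not called without IRI replicate 2 or congested replicate 1, at 0.16 and 0.617. The median of the matrix list was 0.21 without congested replicate 2 and 0.21 without IRI replicate 3, that of the YAP/TEAD list was 0.48 without IRI replicate 1 and 0.20 without IRI replicate 2, and that of the immediate early list was 1.00 without IRI replicate 1, 0.15 without IRI replicate 2, 0.13 without IRI replicate 3, 0 without congested replicate 1 and 0.53 without congested replicate 3. With a trend in transcript length and GC content removed, the median of the matrix list was 0.22 (camera adjusted p = 3.88e-04). In edgeR with the block, removing that trend took the log2 fold change of Fn1 from 0.94 to 0.62. That of Acta2 went from 1.25 to 1.38.

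Cytokines and chemokines rose in the congested kidney with 8 of 12 members above 0 and a median of 0.56 (camera adjusted p = 0.0229, adjusted p = 0.845 with an estimated correlation). Il1b, which encodes interleukin-1 beta, was 2.82-fold higher (edgeR adjusted p = 0.933) and Cxcl10, an interferon-induced chemokine, had a log2 fold change of 0.98 (standard error 0.53). Monocyte and macrophage markers rose with 12 of 14 members above 0 and a median of 0.55 (camera adjusted p = 0.025, adjusted p = 0.845 with an estimated correlation). The scavenger receptor gene Msr1 lay at 1.52 ± 0.788 against 8.38 ± 10.8 CPM (SD, n = 3), and Fcgr1 had a log2 fold change of 1.63 (standard error 0.71). All 5 tested neutrophil markers lay above 0 with a median of 1.73, with a camera adjusted p of 0.0953 in edgeR without the replicate block and 5.49e-06 with it (adjusted p = 0.559 with the block and an estimated correlation). The list was also called without the block by DESeq2 (median 1.51, camera adjusted p = 0.00132) and with a length and GC trend removed (1.98, 0.0222). With an estimated correlation, camera in edgeR without the block gave an adjusted p of 0.845. Csf3r and Mmp9 had blocked log2 fold changes of 2.02 (standard error 0.42) and 2.31 (standard error 0.48). Both rest partly on counts near the floor. Mmp9 lay at 0.09 CPM in IRI replicates 2 and 3, with a smallest count of 1. Csf3r lay at 0.26 CPM in IRI replicate 3, with a smallest count of 3. Neutrophil markers differed by 1.85, 1.41 and 0.63 on average in replicates 1, 2 and 3. Haemoglobin genes, a measure of blood in the tissue, differed by -0.67, -0.33 and 0.45, a mean of -0.18 (SD 0.57) that was 0.19 with a length and GC trend removed. Lymphocyte markers were not tested, since 1 of 12 members passed the filter. Of the 14 neutrophil markers 5 passed it, and of the 24 cytokines and chemokines 12 did. The cytokine list was not called without IRI replicate 3 (adjusted p = 0.977, median 0.01) or congested replicate 1 (0.338, median 0.24), nor the monocyte and macrophage list without the same libraries (0.375 and 0.28, the latter with a median of 0.19). The median of the cytokine list was 1.38 without IRI replicate 1 and 0.27 without congested replicate 2. The neutrophil list was called without IRI replicate 1 (median 3.45, adjusted p = 3.17e-04), congested replicate 2 (2.01, 0.00939) and congested replicate 3 (2.06, 3.30e-04), whereas its median was 0.19 without congested replicate 1 (0.846), 1.07 without IRI replicate 2 (0.336) and 1.17 without IRI replicate 3 (0.829). Without congested replicate 1 the log2 fold changes of Il1b, Msr1, Fcgr1, Csf3r and Mmp9 were 0.24, 0.52, 0.52, 0.35 and 0.50, and without IRI replicate 1 those of Il1b and Mmp9 were 2.65 and 4.82. That of Cxcl10 was 1.85 without IRI replicate 2.

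**Figure D3:**
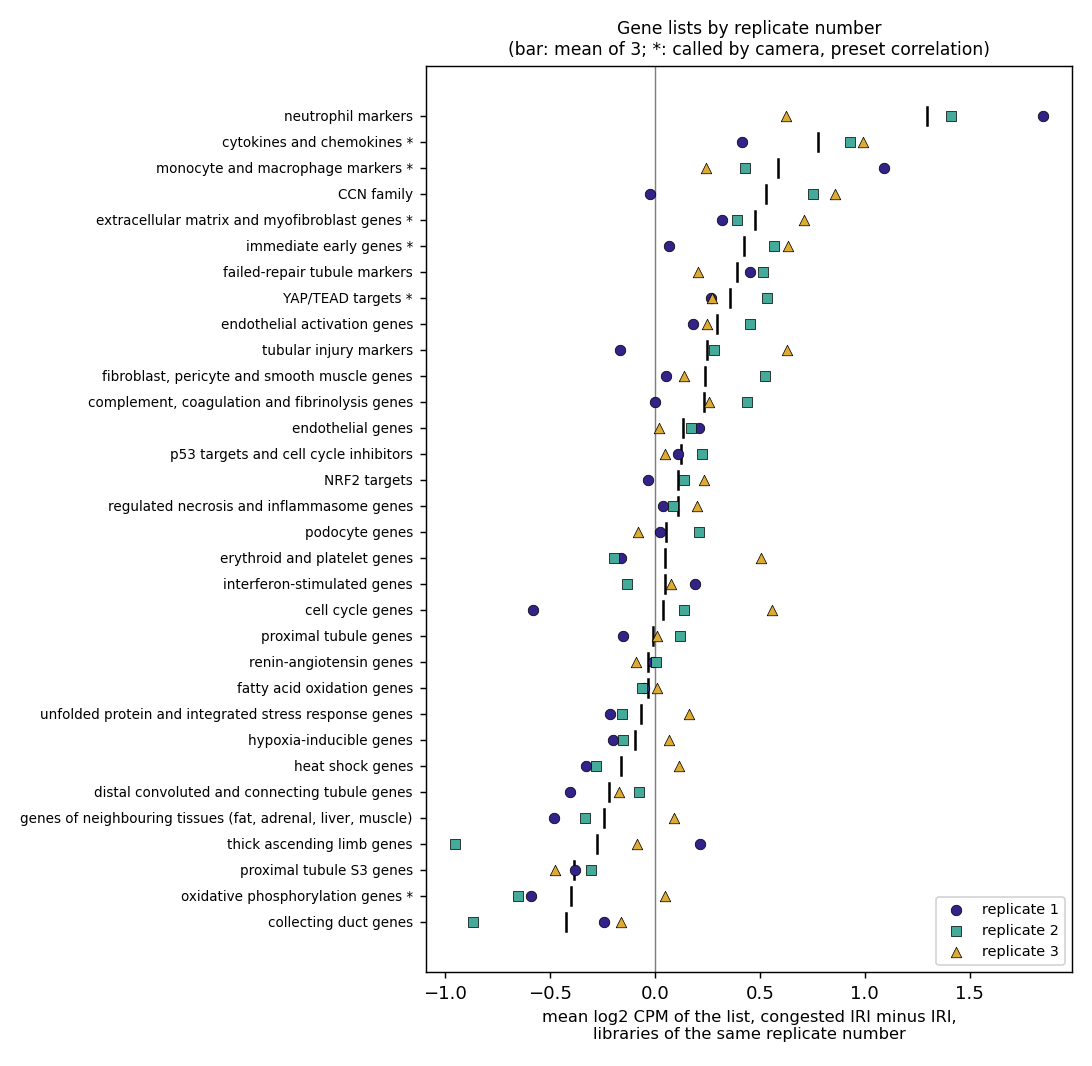
Mean log2 CPM difference, congested IRI minus IRI, of each of the 32 tested gene lists, where points are the differences between libraries of the same replicate number (circle 1, square 2, triangle 3), bars their mean, and asterisks mark the 6 lists that camera called. Neutrophil markers lie above 0 in all 3 replicates, whereas oxidative phosphorylation genes lie below 0 in replicates 1 and 2 and at 0.05 in replicate 3.

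Oxidative phosphorylation genes fell in the congested kidney, with 2 of 22 members above 0, a median log2 fold change of -0.39 and a camera adjusted p of 9.82e-08 (adjusted p = 0.845 with an estimated correlation). Cox5a and Cox5b, both cytochrome c oxidase subunits, had log2 fold changes of -0.67 and -0.70, the latter -0.45 without IRI replicate 2. The difference of the list was -0.59 and -0.65 in replicates 1 and 2 and 0.05 in replicate 3. Members of this list have short transcripts, with a median length of 1763 bases against 3274 over all genes, and with a trend in transcript length and GC content removed the median was -0.23. Fatty acid oxidation genes (9 of 21 members above 0, median -0.08, camera adjusted p = 0.411) and hypoxia-inducible genes (5 of 20, median -0.16, camera adjusted p = 0.19) were not called. The fatty acid oxidation median was -0.02 without IRI replicate 1, -0.15 without IRI replicate 2, -0.17 without IRI replicate 3 and -0.24 without congested replicate 1. The hypoxia median was -0.10 without congested replicate 2. With a length and GC trend removed these medians were -0.12 and -0.08.

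Among tubular segments, the lists of the proximal tubule S3 segment, the thick ascending limb and the collecting duct were called lower in edgeR with the replicate block and not without it. Collecting duct genes were also called without the block by DESeq2 (median -0.46, camera adjusted p = 0.027) and limma-voom (-0.45, 0.0433), against an adjusted p = 0.845 with an estimated correlation in edgeR. For S3 genes 1 of 9 members lay above 0, and camera's adjusted p was 0.217 without and 0.0028 with the block. Their members Cyp7b1 and Slc22a7 had blocked log2 fold changes of -0.84 (standard error 0.18) and -0.94 (standard error 0.22). Of collecting duct genes 0 of 13 lay above 0 (median -0.46, adjusted p = 0.0514 without and 8.64e-04 with the block), among them the water channel gene Aqp2 and the sodium pump regulator gene Fxyd4 at -0.77 and -0.80. Of thick ascending limb genes 0 of 10 lay above 0 (median -0.37, adjusted p = 0.356 without and 0.0495 with the block), including Cldn16 and Ppp1r1a at -0.37 and -0.64. That list differed by 0.22, -0.95 and -0.09 in replicates 1, 2 and 3. It was not called with the block and a length and GC trend removed (camera adjusted p = 0.0636). With the block and an estimated correlation the adjusted p of S3 and collecting duct genes was 0.559 and that of thick ascending limb genes 0.648. Proximal tubule genes (10 of 20 above 0, median -0.01, adjusted p = 0.878), distal convoluted and connecting tubule genes (3 of 10, median -0.18, 0.483) and podocyte genes (7 of 10, median 0.09, 0.767) were not called by edgeR with or without the block, though with the block and a length and GC trend removed distal convoluted and connecting tubule genes were (-0.38, 0.00496, adjusted p = 0.387 with an estimated correlation). Without the block, leaving out IRI replicate 1 called S3 genes (median -0.69, camera adjusted p = 1.07e-04), thick ascending limb genes (-0.77, 3.61e-06), collecting duct genes (-0.55, 3.27e-05) and distal convoluted and connecting tubule genes (-0.47, 0.0107). Leaving out congested replicate 3 called S3 genes (-0.92, 0.0101), thick ascending limb genes (-0.85, 0.0101) and collecting duct genes (-0.77, 0.00104), leaving out congested replicate 2 called collecting duct genes (-0.46, 0.0281) and distal convoluted and connecting tubule genes (-0.49, 0.0302), and leaving out congested replicate 1 called proximal tubule genes higher (0.34, 0.0432). The differences were smaller or opposite without other libraries. Without IRI replicate 3 the medians of S3, thick ascending limb and collecting duct genes were 0.16, 0.04 and -0.15, without congested replicate 1 they were -0.06, -0.03 and -0.07, and without IRI replicate 2 those of thick ascending limb and collecting duct genes were -0.10 and -0.28. Distal convoluted and connecting tubule genes changed sign without IRI replicate 2 (0.04) and congested replicate 1 (0.14). Trpv5, a calcium channel of the distal tubule, had a log2 fold change of 0.91 (standard error 0.30), and the abundant proximal tubule transcript Kap one of -0.81 (standard error 0.38). The other named member of each list went the opposite way. Klk1, whose counts are uncertain, was at -0.52 (standard error 0.37) and Slc4a4 at 0.52 (standard error 0.30). Trpv5 was at 0.57 without congested replicate 2. Kap was at -0.48 without IRI replicate 1. With no block and all libraries, the log2 fold changes of Cyp7b1, Slc22a7, Aqp2, Cldn16 and Ppp1r1a were -0.86, -0.77, -0.77, -0.37 and -0.64. Without congested replicate 1 they were -0.40, -0.29, -0.35, -0.23 and -0.24. Without congested replicate 3 they were -1.70, -1.61, -1.52, -0.64 and -1.43. Without IRI replicate 1 those of Cyp7b1, Slc22a7, Cldn16 and Ppp1r1a were -1.32, -1.20, -0.55 and -1.07. Cldn16 and Ppp1r1a were at -0.05 and -0.24 without IRI replicate 2. Without IRI replicate 3 those of Cyp7b1 and Slc22a7 were 0.06 and -0.35.

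The block also added 3 lists to those called higher: failed-repair tubule markers (8 of 9 members above 0, camera adjusted p = 0.161 without and 0.0109 with it), endothelial activation genes (8 of 11, 0.198 and 0.0383) and complement, coagulation and fibrinolysis genes (12 of 18, 0.249 and 0.0383). With the block and an estimated correlation each had an adjusted p of 0.559. Removing the length and GC trend took the blocked median of failed-repair markers from 0.31 to 0.19. It took the median of endothelial activation genes without the block from 0.40 to 0.25. Ccl2, a monocyte chemoattractant listed among the failed-repair markers, was 2.73-fold higher (edgeR adjusted p = 0.933), and Apln, from endothelial tip cells, had a blocked log2 fold change of 0.74 (standard error 0.23). Tubular injury markers were not called by edgeR without the block (8 of 18 above 0, median -0.06, mean 0.07, camera adjusted p = 0.631) or with it (11 of 18, median 0.10, 0.0589). They were called by DESeq2 with the block (median 0.12, 0.0178) and by edgeR with the block and a length and GC trend removed (0.28, 2.00e-04). With an estimated correlation the latter had an adjusted p of 0.387, and edgeR with the block alone 0.606. Of the members, Cd44 differed by 1.49, 1.02 and 0.91 in replicates 1, 2 and 3. Endothelial genes (9 of 15, median 0.13, adjusted p = 0.249) and fibroblast, pericyte and smooth muscle genes (10 of 11, median 0.27, adjusted p = 0.161) were not called by edgeR, at 0.364 and 0.0519 with the block. The latter list was called by DESeq2 without (median 0.27, camera adjusted p = 0.019) and with the block (0.24, 0.0454) and by limma-voom with the block (0.27, 0.0182). In edgeR it had an adjusted p = 0.845 with an estimated correlation, and 0.598 with the block and an estimated correlation. With a length and GC trend removed its median was 0.11 without and 0.09 with the block, and that of endothelial genes 0.03 and 0.06. The endothelial median was 0.04 without IRI replicate 1, 0.04 without IRI replicate 2, 0.08 without congested replicate 1 and 0.06 without congested replicate 3. Within them Cdh5, a junction protein of endothelium, had a log2 fold change of 0.80 (standard error 0.30) and Notch3, a receptor of mural cells, one of 0.89 (standard error 0.26). Leaving out IRI replicate 1 called failed-repair markers (median 0.53, camera adjusted p = 0.0035), endothelial activation genes (0.70, 0.00216), complement, coagulation and fibrinolysis genes (0.58, 0.00554) and tubular injury markers (0.81, 3.90e-05), and leaving out congested replicate 3 called the same 4 lists (0.40, 0.67, 0.44 and 0.16, at 0.0235, 0.0235, 0.0235 and 0.0274). The fibroblast, pericyte and smooth muscle list was called without IRI replicate 2 (0.41, 0.0125) and without congested replicate 1 (0.56, 2.50e-04), and its median was 0.10 without congested replicate 2 and 0.16 without IRI replicate 1. Without congested replicate 1 the medians of failed-repair markers, endothelial activation genes, complement, coagulation and fibrinolysis genes and tubular injury markers were -0.10, -0.10, -0.06 and -0.60, and the log2 fold changes of Ccl2, Cd44 and Apln were -0.01, 0.22 and 0.21. With all libraries these were 1.45, 1.32 and 0.81. Those of Ccl2 and Cd44 were 2.81 and 2.12 without IRI replicate 1. Without IRI replicate 3 that of Cd44 was 0.88. Without IRI replicate 3 the medians of failed-repair markers, complement genes and tubular injury markers were 0.15, -0.09 and -0.37, and without IRI replicate 2 the median of endothelial activation genes was 0.25.

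The remaining lists did not pass in edgeR with or without the block, but with the block and a length and GC trend removed p53 targets (median 0.15, camera adjusted p = 0.041) and NRF2 targets (0.21, 0.0455) did, at adjusted p = 0.387 and 0.388 with an estimated correlation. Cell cycle genes had a median of 0.16 (14 of 20 members above 0, camera adjusted p = 0.882), p53 targets and cell cycle inhibitors 0.12 (12 of 17, 0.604) and regulated necrosis and inflammasome genes 0.03 (7 of 13, 0.878). NRF2 targets had a median of -0.03 and a mean of 0.02 (7 of 15, 0.878), and interferon-stimulated genes a median of 0.01 and a mean of -0.01 (11 of 18, 0.829). Heat shock genes had a median of -0.20 (1 of 10, 0.161; -0.07 without IRI replicate 1), unfolded protein and integrated stress response genes -0.13 (5 of 16, 0.42) and renin-angiotensin genes -0.07 (3 of 7, 0.89). Erythroid and platelet genes had a median of -0.27 (2 of 8, 0.878) and genes of neighbouring tissues -0.26 (1 of 5, 0.429). Proximal tubule genes had a mean of 0.00 where the median and the camera direction were below 0, and the camera direction of tubular injury markers and NRF2 targets was above 0 where their medians were below it. Cell cycle genes were called without IRI replicate 2 (median 0.73, camera adjusted p = 0.00459), congested replicate 1 (0.54, 0.00231) and, with the opposite sign, congested replicate 2 (-0.68, 0.00394). NRF2 targets (0.32, 0.0107), p53 targets (0.17, 0.0131) and regulated necrosis genes (0.39, 0.0457) were called without IRI replicate 1, and interferon-stimulated genes (0.13, 0.0449) without IRI replicate 2. No member of any list passed over all genes or adjusted over the list alone. With the replicate block 0 members passed over all genes and 26 adjusted over the list alone, 5 each among neutrophil and matrix genes and 4 among cytokines. Of all 33 lists, 32 could be tested, and camera called 6 without and 13 with the block. An estimated correlation and fry each left 0 lists at either fit, while fry's test of change in either direction called 1 list with the block, the cytokines and chemokines (adjusted p = 0.0253).

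Exact tests of library composition cannot pass the threshold with 3 samples per group, so the values are given as measured. Haemoglobin genes held 0.0133% ± 0.00489 of counts in IRI and 0.0123% ± 0.0021 in congested kidney (SD, n = 3, exact permutation p = 0.8). Ribosomal protein genes held 3.27% ± 1.56 and 2.48% ± 0.711 (SD, n = 3, exact permutation p = 0.7), and the 20 most abundant genes 14.2% ± 2.91 and 13.2% ± 2.17 (SD, n = 3, exact permutation p = 0.7). The number of genes detected was 20900 ± 32.5 and 21180 ± 376 (SD, n = 3, exact permutation p = 0.4). Rn18s-rs5 held 0.365% ± 0.193 and 0.157% ± 0.0113 of counts (SD, n = 3), with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 samples allow, and an adjusted p of 0.6 over the 6 measures.

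Across genes, which are not independent replicates, Spearman's rho of the difference with transcript length was 0.533 in replicate 1, 0.597 in replicate 2 and -0.26 in replicate 3. The 10 genes with the smallest p that were higher in the congested kidney, chosen after their values were seen, had a median transcript length of 6258 bases and included Axl, Nid1, Flna, Sorbs2 and Notch3. The 10 that were lower had a median of 1263 bases and included Spa17, Sap30l, Scand1, Arl4d and Rn18s-rs5.

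**Figure D4:**
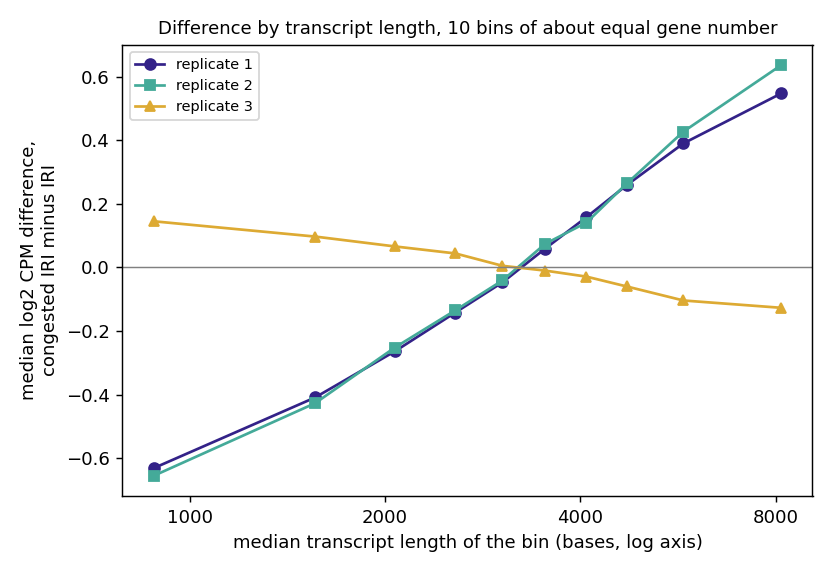
Median log2 CPM difference, congested IRI minus IRI, in 10 bins of genes by transcript length, with the bin's median length in bases on a log scale on the horizontal axis and 1 line per replicate number. The medians run from -0.63 to 0.55 in replicate 1 and from -0.66 to 0.64 in replicate 2, and from 0.15 to -0.13 in replicate 3.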

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

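The fits with a length and GC offset, DESeq2 and limma-voom with the replicate block, those without 1 replicate number in both groups and the count of genes at an unadjusted p under 0.05 were chosen after the data were seen. Counts of called genes stayed at 0 under RLE and upper-quartile factors, both other filters, DESeq2, limma-voom, no robust dispersion, thinned counts, the replicate block and each library left out, with 58 (without IRI replicate 2) to 2721 (without IRI replicate 3) genes at an unadjusted p under 0.05 when 1 library was left out, and 21 without replicate 2 in both groups. That count was 285 in the reported fit, 556 with no filter on low counts, 1008 with the replicate block, 1283 with the length and GC offset and the block, 970 by DESeq2 with the block and 1038 by limma-voom with the block. DESeq2 with the block called 10 genes, 7 higher and 3 lower, 9 with a fold of 2 or more. With the block, leaving out replicate 1 called 12 genes (10 higher, 2 lower, 12 with a fold of 2 or more), leaving out replicate 2 called 9 (6, 3 and 9), and leaving out replicate 3 called 5457 (2844, 2613 and 949), with 6644 at an unadjusted p under 0.05. With the length and GC offset as well, leaving out replicate 3 called 2164 genes (821 higher, 1343 lower, 307 with a fold of 2 or more), with 4380 at an unadjusted p under 0.05. A blocked fit without 1 replicate number has 2 libraries per group and 1 residual degree of freedom, so its counts are weakly founded. Without replicate 3, both remaining pairs differed along with transcript length (Spearman's rho 0.533 and 0.597), and the offset lowered the calls from 5457 to 2164. The cause was not tested beyond this.

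Camera called 6 lists, 13 with the replicate block, 17 with the length and GC offset and the block, 16 by DESeq2 with the block, 14 by limma-voom with the block, and 17, 11 and 4 with the block without replicates 1, 2 and 3 in turn (7 without replicate 3 with the length and GC offset as well). Of the 6 lists, 2 were kept with the block without replicate 3, and 5 with the offset too. With 1 library left out the number was 2 (without IRI replicate 3) to 19 (without IRI replicate 1). An estimated correlation called 0 lists and fry 0, at adjusted p = 0.845 and 0.92 for each of the 6, whose medians (0.344 matrix, 0.293 YAP/TEAD, 0.558 cytokine, 0.546 monocyte and macrophage, 0.327 immediate early, -0.392 oxidative phosphorylation) these tests leave as they are. All 6 were kept under each scaling, filter and tool run on the 6 libraries with the preset correlation. With the block and without replicate 3, the matrix (0.23, camera adjusted p = 0.0739), cytokine (0.309, adjusted p = 0.13), monocyte and macrophage (0.839, adjusted p = 0.0694) and immediate early (0.38, adjusted p = 0.117) lists were not called, and with the length and GC offset too the matrix list was not (0.207, adjusted p = 0.0593). In edgeR with TMM the block changed the calls of 7 lists, given beside the results, and no other call; calls by other fits with the block also stand there.

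Medians of some uncalled lists or their test changed sign. Those of erythroid and platelet genes were -0.196 with no filter and 0.202 and 0.183 with the length and GC offset without and with the block. Those of neighbouring tissues were 0.074 with no filter and -0.027 at a mean CPM of at least 1. By DESeq2 proximal tubule genes stood at -0.009, NRF2 targets at -0.042 and renin-angiotensin genes at -0.065, the last also at -0.05 and -0.038 with the length and GC offset without and with the block, and unfolded protein response genes at 0.04 with that offset and the block. Without the block that offset changed the sign of the medians of tubular injury markers, to 0.144, and NRF2 targets, to 0.155. It changed the size but not the sign of other medians. These were regulated necrosis genes at 0.123, cell cycle genes at 0.092, podocyte genes at 0.029, proximal tubule genes at -0.067, distal convoluted and connecting tubule genes at -0.321, neighbouring tissues at -0.148 and the CCN family at 0.319. The cause was not tested.

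When 1 library, or 1 replicate number in both groups, was left out, medians ran from 0.209 (without congested replicate 2) to 0.462 for matrix genes, from 0.009 (without IRI replicate 3) to 1.379 (without IRI replicate 1) for cytokines, from 0.192 (without congested replicate 1) to 0.88 (without replicate 3 in both groups) for monocytes and macrophages, and from 0 (without congested replicate 1) to 1.005 (without IRI replicate 1) for immediate early genes. Of tubule lists, injury markers ran from -0.596 to 0.806, proximal tubule genes from -0.292 to 0.337, S3 genes from -0.924 to 0.157, thick ascending limb genes from -0.852 to 0.04, and distal convoluted and connecting tubule genes from -0.489 to 0.137. Of the others, podocyte genes ran from -0.076 to 0.145, erythroid and platelet genes from -0.46 to -0.046, neighbouring tissues from -0.264 to 0.335, cell cycle genes from -0.678 to 0.727, p53 targets from -0.01 to 0.178, NRF2 targets from -0.26 to 0.323, regulated necrosis genes from -0.227 to 0.394, unfolded protein response genes from -0.376 to 0.099, complement and coagulation genes from -0.085 to 0.58, interferon-stimulated genes from -0.102 to 0.133 and renin-angiotensin genes from -0.294 to 0.195. Log2 fold changes ran from -0.261 to 1.585 for Ccn1, -0.625 to 1.783 for Ccn2, -0.105 to 0.964 for Vcam1, -0.011 to 2.815 for Ccl2, -1.697 to 0.057 for Cyp7b1, -0.713 to 0.047 for Cldn16, -1.793 to 0.494 for Apoa1, -1.806 to 6.401 for Chil3 and -1.104 to 3.884 for S100a8. The difference in haemoglobin share ran from -0.00378 to 0.000666 percentage points and that of the 20 most abundant genes from -2.55 to 0.362. Medians of other lists ran from -0.255 to 1.585 for the CCN family, 0.187 to 3.447 for neutrophil markers, -0.105 to 0.531 for failed-repair markers, -0.105 to 0.697 for endothelial activation genes, -0.767 to -0.071 for collecting duct genes, 0.097 to 0.556 for fibroblast, pericyte and smooth muscle genes, 0.195 to 0.484 for YAP/TEAD targets, 0.042 to 0.166 for endothelial genes, -0.242 to -0.097 for hypoxia-inducible genes, -0.241 to -0.024 for fatty acid oxidation genes, -0.34 to -0.07 for heat shock genes and -0.614 to -0.255 for oxidative phosphorylation genes. Besides the smaller number of samples, leaving out 1 library makes the groups unequal in replicate number. Replicate 1 of both groups stood apart on the first principal component (68.2% of variance). Injury markers stood at 0.806 without IRI replicate 1 and at -0.596 without congested replicate 1. Cell cycle genes stood at 0.727 without IRI replicate 2 and at -0.678 without congested replicate 2. How much of each range this accounts for was not tested.

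Shares of counts with nuclear genes alone as denominator, and the share of mitochondrially encoded genes, were not run. Total counts of 10865860 to 14350425 limit genes of low abundance, and thinning to the smallest total left 6 lists called and 279 genes at an unadjusted p under 0.05.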

Other observations

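The genes and tests of replicate number, the length and GC tests, the tests of proximal tubule and S3 loss, the tests of pair 3 and the counts over splits other than that of called genes were chosen after the results were seen.

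Spp1 and Lcn2, genes of injured tubules, stood at 40270 and 1210 CPM in IRI replicate 1, 13380 and 207 in IRI replicate 2, and 4792 and 84.8 in IRI replicate 3, and at 59310 and 856, 15330 and 213, and 8798 and 168 in the congested replicates 1, 2 and 3. edgeR's test across replicate numbers gave adjusted p = 0.00353 for Spp1 and 0.00552 for Lcn2. Slc34a1, the phosphate transporter of the proximal tubule, was at 594, 2287 and 2166 CPM in IRI replicates 1, 2 and 3 and at 466, 2384 and 2310 in the congested ones (edgeR adjusted p = 0.00729). Chil3, from macrophages and neutrophils, was at 21.2, 0.768 and 0.353 CPM in IRI and 140, 3.88 and 0.392 in congested kidney (edgeR adjusted p = 0.00122).

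Mki67, a gene of dividing cells, was at 7.88, 35.5 and 9.27 CPM in IRI replicates 1, 2 and 3 and at 3.23, 46.2 and 14.1 in the congested ones (edgeR adjusted p = 0.0133). The cell cycle list had mean log2 CPM of 2.79, 4.10 and 2.64 in IRI and 2.21, 4.24 and 3.19 in congested kidney. Umod, of the thick ascending limb, was at 1174, 4368 and 3864 CPM in IRI and 1548, 2337 and 4501 in congested kidney and did not pass (edgeR adjusted p = 0.0555).

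Matrix genes were higher in congested kidney within pairs, and genes of fibroblasts, pericytes and smooth muscle were so only before a length and GC trend was removed. Against a trend in transcript length and GC content as the whole cause for the matrix list, its blocked median went from 0.36 to 0.244 with the trend removed and the pairs stayed at 0.21, 0.28 and 0.68. For the smooth muscle list the same correction took the blocked median from 0.26 to 0.088 and the pairs to -0.17, 0.31 and 0.16, and a length trend may account for it. More vessel tissue was not excluded there, as the endothelial list differed by 0.134 (SD 0.102 over 3 pairs) against 0.24 (SD 0.25), but its median was as low as 0.042 with 1 library left out and 0.056 with the block and that trend removed. An effect of congestion on these genes was not tested apart from these and stays open.

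The pairs differed in direction. Ccn1 was lower in congested kidney in pair 1 alone. Scaling is argued against there by a pair 1 difference of at most -0.247 over 4 scalings. Exchanged labels in pair 1 stay open. Across genes pair 1 correlated with the mean of pairs 2 and 3 at 0.433 (0.295 with the length and GC trend removed), past the 0.1 set beforehand. This rests on pair 2 (0.587) and not pair 3 (-0.203). With the block, exchanging pair 1 gave 86 genes at an unadjusted p under 0.05, against 1008 as labelled. Exchanging pair 2 gave 53. Such counts cannot decide on an exchange, as they can also follow how the length trends of the pairs line up. Spearman's rho with length was 0.533, 0.597 and -0.26 in pairs 1, 2 and 3. Across genes, which are not independent replicates, pair 3 correlated with the mean of pairs 1 and 2 at -0.211, and at -0.0667 with the length and GC trend removed, so that trend may carry most of the opposition. Exchanged labels in pair 3 are argued against by 15 of 19 lists keeping their sign there, although exchanging that pair gave 4178 genes at an unadjusted p under 0.05 with the block and 831 called. A different response to congestion in pair 3 was not tested and stays open.

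Oxidative phosphorylation genes were lower in congested kidney. The length and GC trend stays open as a cause. The blocked median was -0.39 before and -0.245 after its removal (camera adjusted p = 4.53e-04, adjusted p = 0.506 with an estimated correlation). The corrected pairs stood at -0.28, -0.35 and -0.04. What remained thus lay in pairs 1 and 2, whose differences ran with transcript length (Spearman's rho 0.533 and 0.597). The removal used the longest annotated transcript of each gene, so it may be incomplete and cannot exclude the trend. Loss of proximal tubule cells stays open, since the proximal tubule list differed by -0.007 on average but its members went both ways (SD 0.366 over 20 members, 7 above 0). Loss of S3 cells also stays open. The S3 list differed by -0.387 on average (SD 0.087 over 3 pairs, SD 0.376 over 9 members), against -0.40 in this one. In pairs 1, 2 and 3 the S3 list differed by -0.38, -0.305 and -0.477. The oxidative phosphorylation list differed by -0.589, -0.65 and 0.046, so the averages match but the pairs do not. A lower expression of these genes under congestion stays open as a hypothesis.

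The 10 splits of the 6 libraries are too few for a share under 0.05. edgeR called 0 genes in the real split and at most 0 in the others, and 10 of the splits gave as many. At an unadjusted p under 0.05 the real split gave 285 genes and the highest other 3583, with 7 splits as large, and camera called 6 lists against at most 21, with 8 splits as large. The split that set IRI replicates 1 and 2 and congested replicate 1 against the rest gave the 3583 genes, which points to a structure of the samples. That split also parts the libraries by Spearman's rho of log2 CPM, minus each gene's mean, with transcript length. It was -0.481, -0.473 and 0.0988 in these libraries. In IRI replicate 3 and congested replicates 2 and 3 it was 0.399, 0.495 and 0.275. Whether the length trend gave these genes was not tested. Of the 4 splits that part all pairs, 2 gave at least the 1008 genes of the real one with the block (highest other 4178, which points to a structure of the samples), and 2 at least its 13 lists (highest other 13).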
